A study of Mus musculus with 2 samples.

How the data were processed

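Gene expression was measured in long-term haematopoietic stem cells (LT-HSCs) sorted from the bone marrow of C57BL/6 mice aged 8 weeks. There were 2 arrays, 1 of cells from wild-type mice and 1 of cells from mice lacking cia-cGAS, which the labels describe as a circular RNA. Groups were taken from the genotype label of each sample. Per the labels' protocols, total RNA was extracted with TRIZOL, double-stranded cDNA was primed with oligo dT, and the cDNA was labelled with Cy3 following the NimbleGen expression protocol. Sort markers, the number of cells and whether several animals were pooled are not given in the sources used here.

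The deposited values are intensities on a linear scale, each an RMA summary of the probes of 1 transcript row. RMA (robust multi-array average) is named in the submitters' processing notes, with no version. As generally defined, it subtracts background, equalises the distributions of the arrays by quantile normalization and combines the probes of a row. It therefore removes any difference in total signal between the arrays, so that each difference given here is relative to the other genes. Which arrays were normalized together is not given in the sources used here. Per the file headers and annotation, 44155 of 44171 rows come from 3 probes each, and 1 row holds 5000 random-sequence control probes. That control row read 36.9 on both arrays. Transcripts are placed on the mouse MM9 assembly in the annotation of the files, and coordinates are given as found there, with the counting of the first base as 0 or 1 not stated. The series-wide value table held the same intensities, with differences of at most 1.277e-06 on the log2 scale. Its column medians were 273 for the wild type and 271 for the knockout.

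Intensities were put on the log2 scale and were not normalized again. Of the 44170 transcript rows, 41886 carried a gene ID and symbol in the files and 2284 did not. Symbols were updated by gene ID where possible, with a RefSeq gene table of the GRCm38.p6 assembly used for names alone. It held the gene ID of 39057 rows, and 5650 rows took a newer symbol. The named rows covered 24203 genes, of which 10194 had more than 1 row. The row with the highest mean of both arrays stood for each gene. Near-identical genes such as those of the Ifit, Gbp, Schlafen, Trim30, globin, interferon alpha and histone families can share hybridisation, and single members of these families are uncertain.

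A detection floor was set on each array at the 95th percentile of 1029 rows of olfactory, vomeronasal and taste receptor genes, which blood stem cells are not known to use. It lay at 551 for the wild type (9.11 on the log2 scale) and 500.0 for the knockout (8.97). A gene above the floor on both arrays has a measured fold. For a gene above the floor on 1 array, the fold is the bright value against the floor of the other array and is written as at least that fold. No fold is given for genes below both floors or where this ratio was under 1. The highest values were 15.89 on the log2 scale for the wild type and 15.84 for the knockout. Differences of genes near that top can be compressed. The number of arrays limits the precision.

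The design has no replicates, so no test between groups was run and no p-value is given. Genes with a difference of 1 or more on the log2 scale, knockout minus wild type, were counted in each direction. There were 29 gene lists, fixed before the data were examined, including markers of other marrow cell types. For the 28 lists with at least 5 members above the floor on either array, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 arrays. Counts of list members at 2-fold or more include genes detected on 1 array whose bound reaches 2-fold. Lists share some genes. Genes are named by a rule also fixed beforehand. It takes the 12 characterised genes with the largest difference in each direction among those detected on both arrays, and the 5 with the largest bound in each direction among those detected on 1 array. It adds up to 3 of the highest and lowest members of each list with a difference of at least 1 in size, and a set of anchor genes whatever their values, of which 1 is not reported here. Genes named outside the rule are said to be chosen after their values were seen.

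Alternatives were other floors (the median of all rows, the 99th percentile of receptor rows, none), the mean of all rows of a gene, centring on a loess curve of difference against mean level with a span of 0.3, the series-wide table, folds of 1.5 and 3, and characterised genes alone. For lists they also were the mean in place of the median, values under the floor set to it, and random lists not matched on level. Others were added after seeing the data: genes whose rows all agree, counts without the interferon lists, members detected on both arrays, lists without shared members and 1 member per gene family. A family here was the members of a list whose symbols are the same before the first digit. Such a family can join unlike genes and part similar ones.

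The calculation was tested on simulated data for the knockout against wild-type comparison. A copy of the mean values received noise with the SD found among rows of 1 gene, and 200 of 9413 genes detected on both simulated arrays were changed. A 4-fold change was called at the 2-fold threshold in 100% of cases and a change of 1.5 on the log2 scale in 94% of cases. Of unchanged genes, 0.486% were called. A list of 20 genes shifted by 0.5 lay at percentile 100, and 2 of 100 unshifted lists lay outside the central 95% of random lists. The simulated noise covers disagreement between rows and not the difference between animals. It was drawn for each gene alone and the unshifted lists were random, so genes of a list that vary together are not covered. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.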

Results

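Expression was profiled on single-colour NimbleGen arrays in LT-HSCs, the bone marrow cells that sustain blood formation over the long term. Cells from wild-type mice were compared with cells from mice lacking cia-cGAS, a circular RNA named for cGAS, the cytosolic DNA sensor that acts through STING to induce type I interferon. Each group has 1 array, so no difference given here has a replicate check, and differences describe these 2 samples. Of 24203 genes measured, 9859 lay above the detection floor in the wild type and 10242 in the knockout. The floor was lower in the knockout, at 8.97 against 9.11 on the log2 scale, so these numbers do not compare how many genes were expressed. Above the floor on both arrays were 9242 genes. Across these genes, which are not independent replicates, log2 values of the arrays correlated with r = 0.896, and the median difference between knockout and wild type was -0.04. For the 2896 genes with at least 2 detected rows, the differences of rows of the same gene varied with a pooled SD of 0.37 on the log2 scale. The circular RNA itself was not analysed here, since no row was matched to it by identity or position, and the deletion could not be checked from these values.

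Both arrays carried transcripts typical of mature marrow cells beside those of stem cells. Of 25 neutrophil and granule genes measured, 22 were above the floor in the wild type and 23 in the knockout. The neutrophil gene S100a8 read 14.72 in the wild type and 15.56 in the knockout on the log2 scale, and the globin gene Hba-a1 read 15.41 and 15.22, both genes being chosen after their values were seen. The stem cell surface receptors Procr and Slamf1 lay below the floor on both arrays, whereas Kit and Ly6a, which encodes Sca-1, were detected on both. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y were detected on both arrays, with differences from -0.31 to 0.17, and Xist was below both floors, all being members of a list of sex-linked genes fixed beforehand.

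Among the genes detected on both arrays, 497 were at least 2-fold higher in the knockout and 387 at least 2-fold lower. The largest differences were upward: 138 genes were at least 4-fold higher against 24 lower, and 47 were at least 8-fold higher against 1 lower. A further 104 genes detected in the knockout alone and 54 detected in the wild type alone differed by at least 2-fold against the floor. The interferon-stimulated and interferon-induced lists held 40 of the 497 higher genes and 0 of the 387 lower ones. When all rows of a gene were averaged, 384 genes were higher and 199 lower. Among the 2896 genes with several detected rows, 116 were higher and 39 lower in every detected row.

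**Figure D1:**
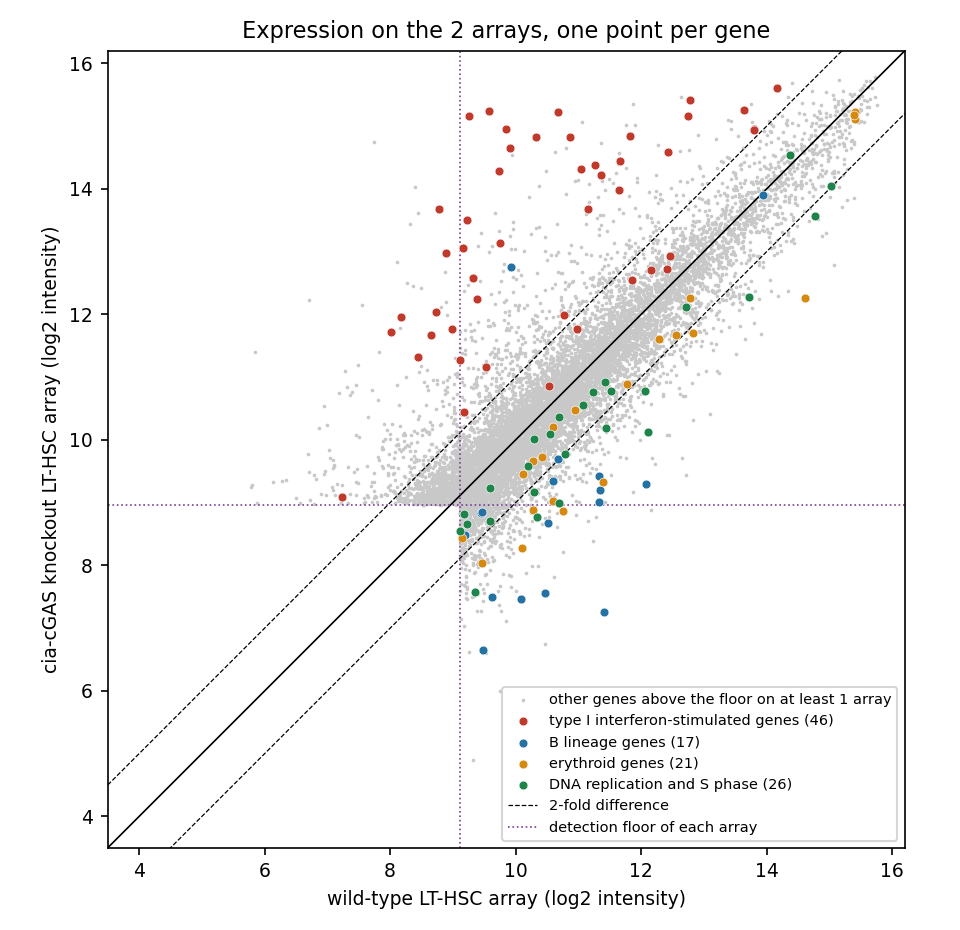
Log2 intensity of each gene in the wild-type array (horizontal axis) and the cia-cGAS knockout array (vertical axis), for genes above the floor on at least 1 array. Dashed lines mark a 2-fold difference and dotted lines the floors of 9.11 and 8.97; the 46 interferon-stimulated genes lie above the diagonal, and the 21 erythroid genes and 16 of 17 B lineage genes lie below it.

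The largest difference among genes detected on both arrays was that of Cxcl10, a chemokine induced by interferon, which was 59.7-fold higher in the knockout. Its log2 intensity was 9.26 in the wild type and 15.16 in the knockout (gene ID 15945, transcript on chromosome 5 from 92775664 to 92777882). The Schlafen gene Slfn5 was 50.5-fold higher, with differences of 3.73 to 5.66 among its rows. The antiviral genes Ifit2, Ifit1, Mx1 and Ifit3 were 34.3-fold, 26.6-fold, 23.6-fold and 23.2-fold higher. Fgl2 was 24.2-fold higher, Cmpk2 22.6-fold, the DNA-binding p200 gene Ifi204 19.5-fold, the helicase gene Ddx60 16.1-fold, Herc6 15.5-fold (rows from 2.34 to 5.16) and the inflammatory caspase gene Casp4 15.5-fold. Genes detected in the knockout alone included Ifit1bl1 (at least 49.8-fold higher), the early activation marker Cd69 (at least 30.3-fold), Mx2 (at least 23.7-fold), Gbp5 (at least 22.9-fold) and Ifi205 (at least 20.1-fold).

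The genes with the largest negative differences included B lineage genes and genes of DNA synthesis and chromatin. The phospholipid transporter gene Abcb4 was 9.67-fold lower in the knockout (gene ID 18670, chromosome 5 from 8893948 to 8941114). The histone gene H2bc8 was 7.62-fold lower and Dut, which encodes dUTPase, was 6.42-fold lower (rows from -2.68 to -1.67). Ebf1, a transcription factor of early B cells, was 6.89-fold lower from its brightest row, and its rows differed from -2.78 to -1.36. The B cell genes Cd72, Tnfrsf13c and Dntt were 6.14-fold, 5.15-fold and 4.97-fold lower, although the other row of Tnfrsf13c differed by -0.80. The haemoglobin gene Hbb-b2 was 5.09-fold lower, E2f4 5.07-fold (its other row -1.48), Ces2g 6.54-fold, Hddc2 5.33-fold and the splicing factor gene Srsf10 5.70-fold, although the rows of Srsf10 ranged from -2.51 to 0.09. Genes detected in the wild type alone included the histone gene H2ac15 (at least 9.10-fold lower in the knockout), the B cell transcription factor genes Pax5 (at least 5.45-fold) and Ikzf3 (at least 4.97-fold), Crocc2 (at least 4.55-fold) and Mageb16 (at least 3.44-fold).

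**Figure D2:**
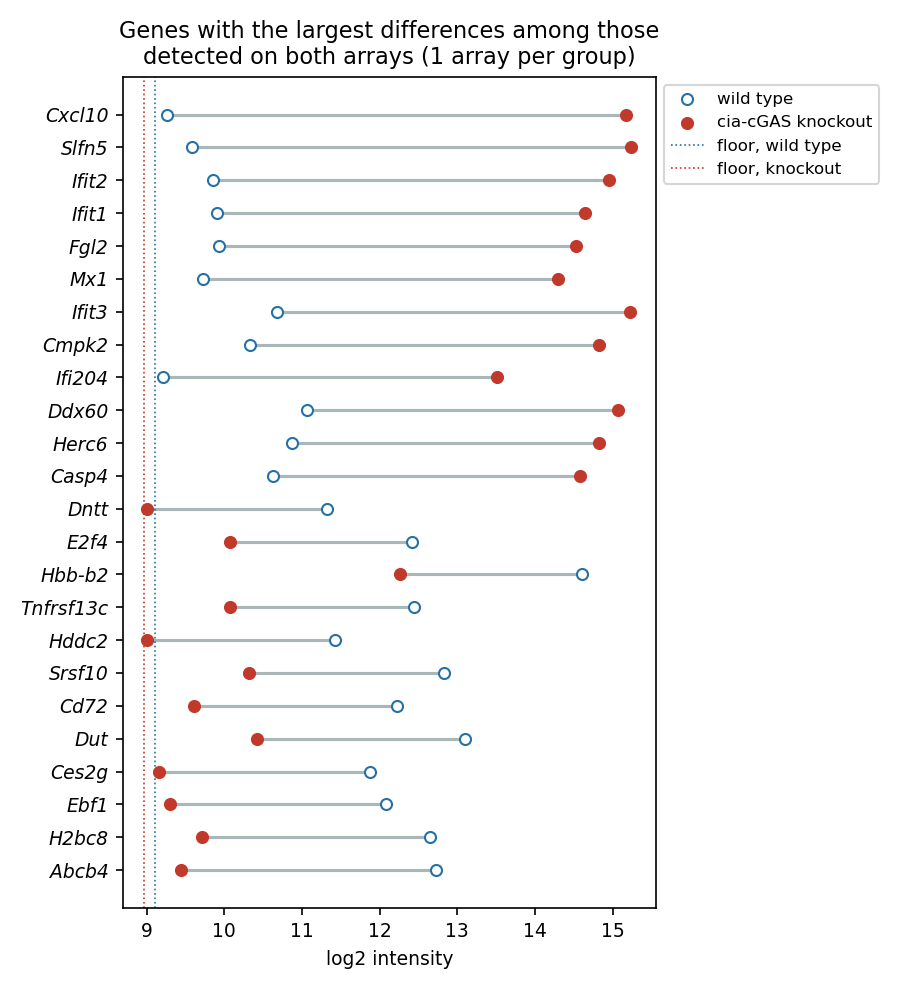
Log2 intensity in the wild type (open circles) and the knockout (filled circles) of the 12 genes with the largest positive and the 12 with the largest negative difference among those detected on both arrays; dotted lines mark the floors. Upward differences run to 5.90 for Cxcl10 and downward ones to -3.27 for Abcb4.

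Type I interferon-stimulated genes were higher in the knockout across the list. Of 46 members above the floor, 39 were at least 2-fold higher, 0 were at least 2-fold lower, and all 46 had a positive difference. The median difference was 2.87, a 7.30-fold higher level, at percentile 100 of random lists, whose central 95% ran from -0.20 to 0.14. With values under the floor set to it, the median was 2.65. The transcription factor gene Irf7, itself induced by interferon, was at least 7.63-fold higher. Another row of Irf7, above the floor on both arrays, differed by 1.16. The ubiquitin-like gene Isg15 was 7.32-fold higher. The neutrophil list, measured on the same arrays, was also higher, with a median of 0.48.

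Genes induced by type II interferon were higher as well, with 10 of 17 at least 2-fold higher, 0 lower and a median of 1.72 (percentile 100). All 10 encode guanylate-binding proteins or immunity-related GTPases, of which Gbp2 and Gbp3 were 14.4-fold and 12.5-fold higher. The MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 differed by 0.17, -0.09, -0.24 and 0.20 and Irf8 by -0.27, genes chosen after their values were seen. In the list of nucleic acid sensing and interferon signalling, 8 of 22 genes were at least 2-fold higher and 0 lower, with a median of 0.92 (percentile 100). Under the alternatives that median ran from 0.30 with no floor to 1.36 with rows averaged, with 0.33 for the floor at the median of all rows, 0.41 over members detected on both arrays, 0.44 without members of other lists and 0.55 with values under the floor set to it, each above the central 95% of random lists. Of the RNA sensor genes, Ifih1 was at least 14.7-fold and Ddx58 14.8-fold higher, and the Z-nucleic acid sensor gene Zbp1 was 9.70-fold higher, its other row differing by 2.14. The gene of the DNA sensor cGAS, Cgas, was below the floor in the wild type and at least 3.58-fold higher in the knockout (gene ID 214763, chromosome 9 from 78278324 to 78290954). Sting1, the gene of its downstream adaptor, differed by -0.47. The interferon genes themselves lay near the floor, with 5 of 14 detected, a median of 0.51 and percentile 89.95. The list came to lie above the central 95% with the floor at the median of all rows (0.49, percentile 99.35), with no floor (0.47, percentile 99.76) and with the mean in place of the median (1.17, percentile 99.28). With values under the floor set to it, the median was 0.23 and stayed within that range (percentile 94.56). Ifnb1 was at least 1.17-fold higher, and Ifna2 passed the knockout floor without reaching that of the wild type.

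Inflammatory, cell death and antigen presentation genes also had positive median differences, below those of both lists of interferon-induced genes. Of 16 inflammatory and NF-kB target genes, 7 were at least 2-fold higher and 0 lower, with a median of 1.23 (percentile 100), or 0.69 (also percentile 100) with values under the floor set to it. The chemokine gene Ccl3 was 8.13-fold higher and the cytokine gene Il1b 7.37-fold, while Cxcl2 was 6.77-fold higher from its brightest row and its other row differed by -0.01. Neutrophil and monocyte lists, measured on the same arrays, had positive medians too, 0.48 and 0.44. Of 19 apoptosis and necroptosis genes, 8 were at least 2-fold higher and 0 lower (median 0.77, percentile 100, and 0.51 with no floor). These included the necroptosis effector gene Mlkl, 8.21-fold higher, the death ligand gene Tnfsf10, at least 3.22-fold higher, and Bcl2l11, 2.54-fold higher. None of 16 genes of MHC class I and antigen processing reached 2-fold, and their median of 0.39 lay at percentile 99.6. With the mean in place of the median, that list lay at percentile 94.3, and with 1 member per gene family at 95.8.

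**Figure D3:**
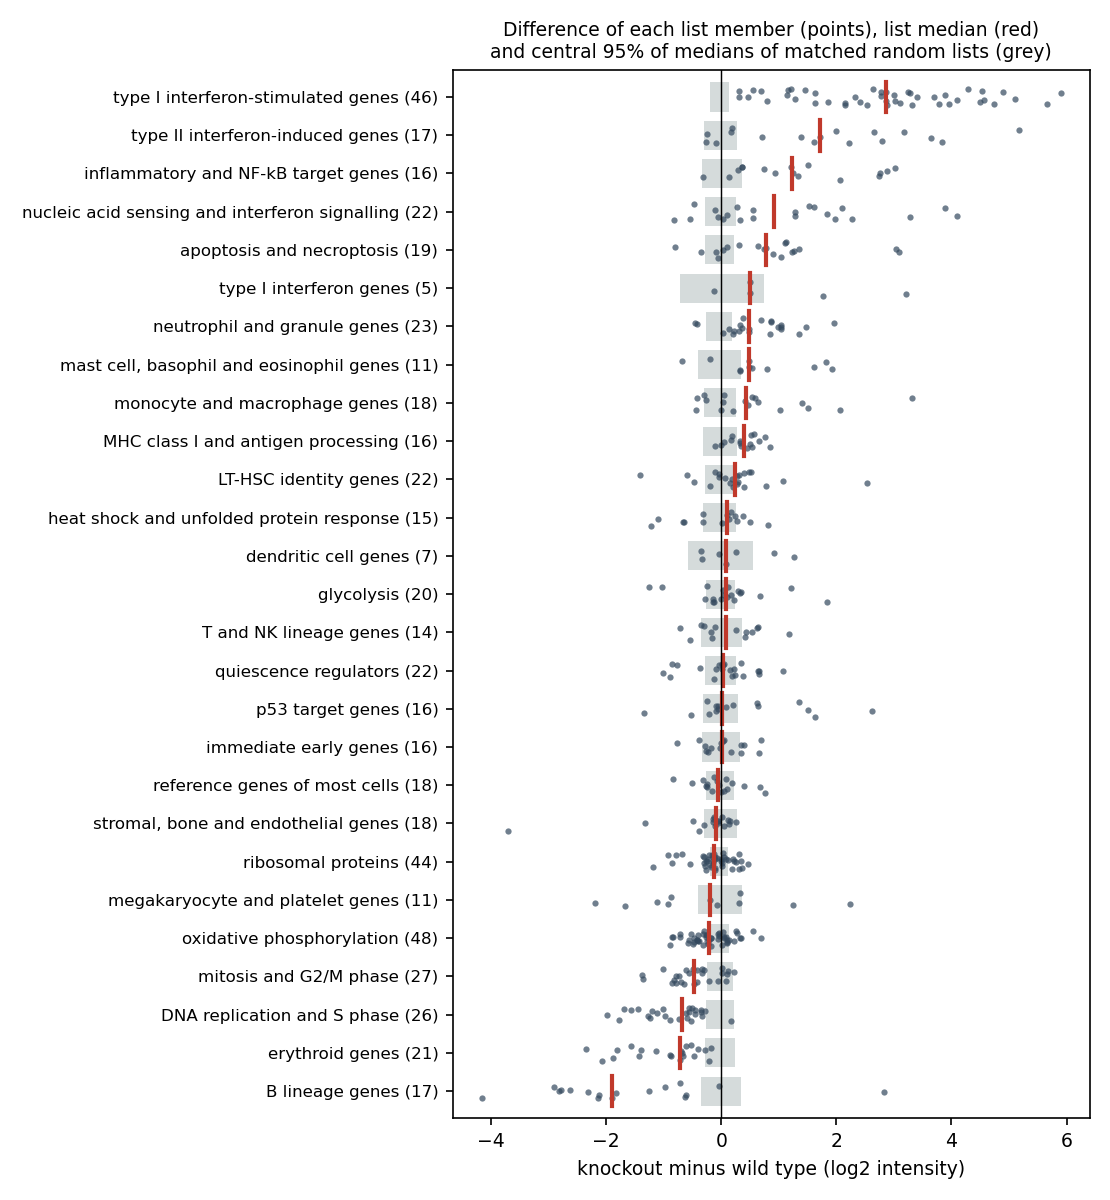
Difference between knockout and wild type on the log2 scale (horizontal axis) for each detected member (points) of 27 gene lists (rows, with the number of members), the list median (red line) and the central 95% of medians of matched random lists (grey). The medians run from -1.90 for B lineage genes to 2.87 for type I interferon-stimulated genes.

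The list of LT-HSC identity genes was not set apart from random lists. Of 32 members measured, 22 were above the floor, 0 were at least 2-fold higher and 1 was lower, with a median of 0.24 (percentile 96.8). With values under the floor set to it, the list lay at percentile 99.01. Kit differed by 0.30 and Ly6a by 0.40. The transcription factor gene Tal1, detected in the wild type alone, was at least 2.20-fold lower in the knockout. Hoxb4 and Hlf, detected in the knockout alone, were at least 1.32-fold and 1.20-fold higher. Quiescence regulators had a median of 0.04 (percentile 64.5), with 0 of 22 genes higher and 1 lower. That gene was the transcription factor gene Foxo3, 2.02-fold lower, with differences of -1.01 to 0.20 among its rows. The cell cycle inhibitor gene Cdkn1a differed by 0.65, and Cdkn1c, Rbl1, Cdk6 and Ccnd1 passed the floor in the knockout alone, with bounds under 2-fold.

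Cell division genes were lower in the knockout. Of 26 DNA replication and S phase genes, 9 were at least 2-fold lower and 0 higher, 25 had a negative difference, and the median of -0.68 lay at percentile 0. The methylation maintenance gene Uhrf1 was 3.96-fold lower, the flap endonuclease gene Fen1 3.22-fold and the replication licensing gene Cdc6 at least 1.31-fold. Of 27 mitosis and G2/M phase genes, 2 were at least 2-fold lower and 0 higher (median -0.46, percentile 0.01). The kinase gene Nek2 was 2.57-fold lower from its brightest row, the other differing by -0.14, and Cenpf was 2.01-fold lower. Cdca3 was at least 1.18-fold lower, Mki67 differed by -0.64 and Ccnb1 by -0.30. The B lineage and erythroid lists were lower on the same array, with medians of -1.90 and -0.71.

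Markers of other marrow cells moved in both directions. Of 17 B lineage genes, all detected in the wild type and 8 in the knockout, 9 were at least 2-fold lower and 1 higher (median -1.90, percentile 0). With values under the floor set to it, the median was -1.12, also at percentile 0. The surrogate light chain gene Vpreb2 was at least 2.82-fold lower and the recombination gene Rag2 at least 1.43-fold, while Jchain, the joining chain of secreted antibodies, was 7.14-fold higher. Of 21 erythroid genes, 7 were at least 2-fold lower and all 21 had a negative difference (median -0.71, percentile 0). The membrane skeleton genes Ank1 and Sptb were 4.19-fold and at least 3.44-fold lower, and Gata1 differed by -0.70. Neutrophil and granule genes were higher, with 5 of 23 at least 2-fold higher, 0 lower and a median of 0.48 (percentile 100), or 0.79 with rows averaged. The integrin gene Itgam was 2.78-fold higher (its other detected row 0.84), Padi4 2.55-fold and Ms4a3 at least 1.40-fold, while the granule enzyme gene Mpo differed by -0.41. Of 18 monocyte and macrophage genes, 5 were at least 2-fold higher and 0 lower (median 0.44, percentile 99.9). Among them Fcgr1 and Ms4a6c were at least 2.11-fold and 3.51-fold higher and Ctss was 2.86-fold higher. Of the 18 genes, 13 had a positive and 5 a negative difference. The latter included Cd14 (-0.44), C1qb (-0.42) and Cd68 (-0.29), chosen after their values were seen.

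Mast cell, basophil and eosinophil genes had a median of 0.48 (percentile 99.5), with 2 of 11 at least 2-fold higher. These were Mcpt8, at least 3.22-fold, and Hdc, 3.04-fold, and Cpa3 was at least 1.75-fold higher. Megakaryocyte and platelet genes were mixed, with 2 of 11 higher, 2 lower and a median of -0.19 (percentile 18.7), but -0.53 (percentile 0.22) with the floor at the median of all rows and -0.44 (percentile 1.67) with rows averaged. The chemokine gene Ppbp was 4.55-fold and Itga2b 2.16-fold lower, Pf4 was at least 1.48-fold lower, and Plek and Thbs1 were 4.71-fold and 2.37-fold higher. T and NK lineage genes had a median of 0.07 (percentile 62.5), dendritic cell genes 0.08 (percentile 58.7) and stromal, bone and endothelial genes -0.09 (percentile 30.9), or -0.34 (percentile 1.48) with the mean in place of the median. The bone matrix gene Ibsp was at least 2.82-fold lower and the adipocyte gene Adipoq at least 1.22-fold lower. Cd8a and Clec9a were at least 1.24-fold and 1.19-fold higher.

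Oxidative phosphorylation genes had a median of -0.22 (percentile 1.21), with 0 of 48 genes past 2-fold in either direction. When 1 member per gene family was kept, the one nearest to 0, the median was 0.01. Of 16 p53 target genes, 3 were at least 2-fold higher and 1 lower (median 0.02, percentile 59.2). Fas, a death receptor gene, was 6.12-fold higher, Mdm2 2.85-fold and Plk2, chosen after its value was seen, 2.54-fold. Pmaip1 was at least 1.41-fold higher. Aen was 2.52-fold lower from its brightest row, with differences of -1.33 to 0.44 among rows. Glycolysis genes had a median of 0.08 (percentile 77.8), with Hif1a 3.56-fold and Hk2 2.32-fold higher, Pdk1 2.04-fold lower and Slc16a3 at least 1.17-fold lower. Ribosomal protein genes had a median of -0.12 (percentile 17.5), and 1 of 44, Rps21, was 2.28-fold lower. Heat shock and unfolded protein response genes had a median of 0.10 (percentile 83.5), with the chaperone gene Hspd1 2.15-fold lower. Hsph1 was 2.32-fold lower from its brightest row, but its difference was 0.37 when its rows were averaged. Immediate early genes had a median of 0.01 (percentile 51.8), and 0 of 16 passed 2-fold. Myc differed by -0.23. The medians of the p53 target, T and NK, dendritic cell and immediate early lists changed sign under some alternatives. The heat shock and unfolded protein response list had a negative mean, -0.11. All of these values lay within the central 95% of random lists.

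The control list of reference genes stayed within the central 95% of random lists. Reference genes of most cells had a median of -0.05 (percentile 46.9), which became 0.01 after loess centring, and 0 of 18 passed 2-fold. The receptor genes set the floor of each array, so they are no independent control. The number of them above it follows largely from that choice. Of 934 receptor genes measured, 62 lay above the floor on either array, with a median of -0.14 (percentile 5.75) and 0 higher and 2 at least 2-fold lower. Among these Olfr45 was 2.44-fold lower (its other row -0.50), Olfr1239 at least 1.51-fold and Vmn2r7 at least 1.16-fold, and Olfr813 was at least 1.88-fold higher. Of the 28 lists with enough members, 9 lay above and 5 below the central 95% of random lists, and 14 lay within it.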

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

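The comparisons above use rows that carry a gene ID. Among the 2284 transcript rows without one, 466 were above the floor on both arrays, and the wild-type array served as the control level. Of these 466 rows, 23 were at least 2-fold higher in the knockout and 22 at least 2-fold lower, with a median difference of -0.05. They drew attention because they are signals outside the measurements compared above. No explanation was tested for them.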

How the results depend on the processing

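The alternatives with agreeing rows, without the interferon lists, with members detected on both arrays, without shared members and with 1 member per gene family were chosen after seeing the data. The counts of higher and lower genes, 497 and 387, depended on the floor, the fold and the rows used. They were 291 and 241 with the floor at the 99th percentile of receptor rows, 1411 and 1435 with no floor, 1057 and 1154 at 1.5-fold, and 221 and 72 at 3-fold. Averaging all rows of a gene gave 199 lower genes, 188 of them shared with the 387, and 384 higher genes, 346 of them shared with the 497. Rows agreed for 116 higher and 39 lower genes among 2896. The higher floor lets 5559 genes enter in place of 9242, averaged rows let 7074 enter and no floor lets 24203 enter. Agreeing rows lets in fewer genes and by construction also asks more of each, and these were not told apart. With averaged rows fewer genes enter, but lower genes fell further, from 387 to 199, than higher genes, from 497 to 384. Why they did so was not tested. The median of the LT-HSC identity genes, 0.24, moved past the central 95% of random lists with values under the floor set to it (0.23, percentile 99.01) and against random lists not matched on level (0.24, percentile 97.6). It fell to 0.11 with no floor, 0.16 with the floor at the median of all rows and 0.17 with rows averaged, within that range; the causes were not tested. The other 4 main lists kept their sign and their place inside or outside that range under the alternatives run, with 2.63 to 2.91 for interferon-stimulated, -0.86 to -0.59 for S phase, -0.47 to -0.41 for mitosis and 0.02 to 0.08 for quiescence genes. Oxidative phosphorylation reversed to 0.0116 with 1 member per family, which by construction keeps the member nearest 0. Among the named genes, Hsph1 reversed to 0.37 with rows averaged, which brings in 2 dimmer rows below the floor on both arrays. For the other lists, 6 values came to lie outside the central 95%, among them 3 of the type I interferon genes, and 3 within it, oxidative phosphorylation included, and 64 values of named genes moved by more than the SD of 0.37 between rows, with averaged rows or values set to the floor. The series-wide table holds the same values, so it tests nothing. No paired analysis was possible because each group has 1 array. For the same reason no array could be left out. Signal over the floor limits Ifnb1, Hoxb4, Hlf and other dim genes to bounds under 2-fold.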

Other observations

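The tests of the myeloid share, of interferon unrelated to genotype, of dim signal, of RNA without a poly(A) tail and of dividing precursors were chosen only after the result was seen, as were the gene families below and the minimum of dim members asked of the plasma cell list. Single genes named in this part were chosen after their values were seen, apart from those already named by the rule.

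Several gene families outside the fixed lists, or wider than them, differed between the arrays. Their medians kept their sign after loess centring, which could move them little on quantile-normalized arrays. Of guanylate-binding protein and immunity-related GTPase genes, all 13 detected with Gbp, Irgm, Igtp or Iigp symbols were at least 2-fold higher in the knockout. Their median difference was 2.65 on the log2 scale. Tgtp1, a gene of the same kind outside this count, was 9.08-fold higher. At least 2-fold higher were also 10 of 11 interferon-inducible p200 genes (median 2.67), 6 of 7 Schlafen genes (median 3.26) and 4 of 4 Trim30 genes (median 3.503). Members of these families resemble each other, so these counts do not stand for independent genes. Of 19 C-type lectin genes, taken by their Clec symbols, 7 were at least 2-fold higher and 0 lower, with differences of 2.91 for Clec4d, 2.35 for Clec4e and 2.30 for Clec5a. Of 7 Toll-like receptor genes, all had a positive difference and 2 passed 2-fold. The neutrophil and monocyte lists were also higher on the same arrays, with medians of 0.48 and 0.44.

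Histone genes of the replication-dependent and linker classes mostly stood lower. Of 41 detected, 22 were at least 2-fold lower, 0 were higher and the median difference was -1.18. Most H3 histone genes moved less. H3c1, H3c15, H3c8 and H3c11 differed by -0.45, -0.44, -0.37 and -0.22, and H3c6 and H3c13 by 0.18 and 0.22. H3c7 differed by -1.24 but lay below the floor in the knockout. Outside the H3 genes, H1f2 and H2bc4 differed by 0.01 and 0.03. Genes of the spliceosomal snRNP and SR proteins, which remove introns, had a median of -0.71, with 6 of 27 at least 2-fold lower and 0 higher. Snrpa1 differed by -1.78 and Snrnp70 by -1.63. Within antigen presentation the members differed: the classical class I genes H2-K1 and H2-D1 differed by -0.01 and 0.05, at log2 intensities of 14.16 and 15.26 in the wild type, while Tap1 differed by 0.84 and Psmb8 by 0.65.

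Interferon-stimulated genes stood higher in the knockout, with a median of 2.87. An intensity-dependent trend left in these values is argued against. Grouped by mean level, genes detected on both arrays had median differences between -0.08 and -0.02, and loess centring left the list median at 2.91. Quantile normalization removes most of such a trend beforehand, so the normalization step itself was not tested. Cross-hybridisation within near-identical gene families is argued against as the whole cause, as far as such families share their symbol before the first digit. The median over 1 member per family taken that way, the one nearest 0, was 2.66. A larger share of the neutrophils and monocytes that both arrays hold, with expression in each cell unchanged, would have to raise their own genes as much. Over members under a mean level of 13, where the scale is not compressed, the higher of the upper quartiles of both myeloid lists was 1.04, below the lower quartile of 1.63 of the interferon-stimulated genes. That comparison cannot tell which cells of the sort carried the higher RNA, stem cells or others, because each array measured the pooled RNA of a sort. Interferon in the knockout animal for a reason other than its genotype cannot be told apart from an effect of the deletion, because there was 1 knockout array, and both may hold.

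B lineage and erythroid genes stood lower in the knockout, with medians of -1.90 and -0.71, or -1.12 and -0.69 with values under the floor set to it. A general loss of dim signal on the knockout array cannot be decided by these lists. Quantile normalization evens out a fall shared by genes of one level, and the lists had already been compared with random lists of their level. With no floor, the medians of both lists, -1.17 and -0.70, also lay below the central 95% of such random lists. The 9 erythroid genes at a mean level of 11 or above, far over the floor, had a median of -0.69. A smaller share of B-lineage cells in the knockout sort is a candidate explanation for the B cell part. A further list of 26 B-lineage genes, not looked at before, had 17 members above the floor, 14 of them lower, and a median of -0.68, where a median of -0.5 or lower had been predicted. The brightest rows were those of Cd2, at 13.76 in the wild type and 12.10 in the knockout, and Cd37, at 12.65 and 12.48, whereas Cd180 differed by 1.36 the other way. Several of these genes are also used by other blood cells. A stem cell sort that excludes lineage markers would remove mature B cells. Whether this sort did so is not given, and both arrays carried transcripts typical of mature marrow cells. Lower expression of the same genes within the sorted stem cells was not tested and stays open, as does the erythroid part.

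DNA replication and histone genes stood lower in the knockout, with medians of -0.68 and -1.18, although most H3 histone genes moved less. Labelling was primed with oligo dT, and most histone RNAs lack a poly(A) tail, so that the capture of such RNA could differ between samples. As the whole cause this is argued against by the DNA replication list, whose RNAs carry the tail and whose median of -0.68 lay below the central 95% of random lists. It stays open for the histone genes alone. Fewer dividing B and erythroid precursors in the sort and slower division of the stem cells cannot be told apart, because each array measured the pooled RNA of a sort. The mitosis list, with a median of -0.46, was lower as both would have it.

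Jchain stood higher, with a difference of 2.84, while B precursor genes stood lower. Of 12 detected immunoglobulin genes, 8 had a positive and 4 a negative difference (median 0.64), and 1 was at least 2-fold higher and 2 lower. Ighg3, below the floor in the wild type, was at least 2.88-fold higher, Igk and Igkv4-59 differed by 0.91 and 0.72, and Ighm and Iglv1 by -1.12 and -1.06. More plasma cells in the knockout sort was the hypothesis, with a predicted median of 0.5 or higher over 12 plasma cell genes. The 8 members above the floor had a median of -0.15 (percentile 24.4 of matched random lists), with Ell2 differing by 1.73, Prdm1 by -0.16 and the plasma cell marker Sdc1 by -0.10. A median of 0.2 or lower had been set beforehand as counting against the hypothesis. That bound was poorly chosen, since only 2 of the 8 members, Ell2 and Prdm1, which moved apart, lay under a log2 level of 10 in the wild type and bright members such as Sec11c, at 13.84, could hide a small share. The predicted rise was not seen, and a small added share of plasma cells stays open.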
